A study of Mus musculus with 68 samples.

How the data were processed

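Gene expression was measured with 68 Affymetrix mouse gene arrays on RNA from motor neurons that had been derived from mouse embryonic stem cells. The deposited table held log2 values for 35556 transcript clusters, the probe sets that stand for transcripts on these arrays. The authors made these log2 values with RMA, which corrects background, normalizes quantiles across arrays and summarises probes, through the oligo package, per the submitters' processing notes. The versions of these tools and the annotation build are not given in the sources used here. No scanner intensities were analysed here, so neither the background nor the detection of single probes was examined, and for arrays only their number limits the precision stated. Quantile normalization can hide a shift of most genes in one direction, although array medians still ran from 7.08 to 7.84.

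Genes were named through the array's probe annotation and a RefSeq gene table. Of the 35556 clusters, 23410 were in that annotation. Exactly 1 symbol belonged to 21789 of them, several to 1621, and 12146 clusters had none. The entrez identifiers of 21698 single-symbol clusters matched the RefSeq table and 0 were renamed. Clusters with several symbols or none were left out. For the 999 genes with more than 1 cluster, the cluster with the highest mean over all 68 arrays was kept, which left 19938 genes. All array columns were mapped to samples by name.

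The submitters' labels gave 31 groups: 45 arrays of cells sorted for a CD2 reporter and 23 of cells sorted for a CD14 reporter, hybridised in 8 batches numbered 0 to 7. Each induced line was compared with YFP arrays of the same reporter, the control that the series description names. All 68 arrays entered a single limma model with 1 term per group and 1 per batch (37 model columns, 31 residual degrees of freedom, 6.08 prior degrees of freedom), fitted with lmFit and eBayes. Batches 4 and 5 held no YFP array and batch 6 none of CD2. They were tied to the CD2 controls through groups also in other batches. Batch 0 held only 1 group, so its arrays entered no comparison. There were 35 comparisons: 27 with YFP, 7 between lines, and 1 of the effect of Pou3f1 in CD14 cells minus that in CD2 cells. Adjusted p-values are from limma, two-sided, with Benjamini-Hochberg adjustment over the 19938 genes of each comparison. Genes with adjusted p under 0.05 are said to have risen, fallen or changed. Fold changes are differences of log2 values, and ± gives the standard error of the fit unless stated otherwise. The labels do not say whether replicate arrays came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Same-batch replicates correlated across genes at 0.987 to 0.999 (21 pairs) and those of different batches at 0.974 to 0.994 (26 pairs). At most 8 genes had identical values in a pair, so none was treated as a copy.

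Gene lists, tests, the model, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took each line's induced gene. For 7 comparisons with YFP (Pou3f1 in CD2 and in CD14, Pou3f1+Hoxa5, Notch1ICD 30, NERT 30, Lhx3 in CD2 and DNLhx3 in CD2) it took the 10 largest rises and 10 largest falls among called genes whose batch-adjusted value lay on the same side of the mean YFP value in every array of the group. For the other comparisons it took 3 and 3. It added at most 4 called members per list and comparison, and Pou3f1, Hoxa5, Pcdh10, Alcam, Ptn, Isl1, Mnx1, Lhx3, Hes5 and Hey1 in any comparison. RIKEN, predicted and olfactory receptor genes were counted but not named. Genes named outside the rule are said to be so.

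Lists came from general knowledge of the field and not from the study. Measured genes numbered 12 for phrenic motor neuron (Pou3f1, Hoxa5, Hoxc5, Hoxc4, Alcam, Pcdh10, Ptn, Cdh6, Cdh9, Cdh10, Negr1 and Tshz1), 13 for generic motor neuron, 10 for lateral motor column, 4 for median motor column, and 5 for hypaxial and preganglionic motor column. There were 14 for Hox paralogues 1 to 5, 23 for Hox paralogues 6 to 13, 12 for Notch targets, and 13 for Notch ligands and proneural factors. Axon guidance receptors and ligands had 41, cadherins and protocadherins 29, BMP and TGF-beta response 14, and neurotrophic and neuropeptide 14. Cell cycle had 17, synaptic and mature neuron 18, and stress and apoptosis 13. Marker lists of other cell types covered neural progenitor and radial glia (16), ventral interneuron (15), dorsal interneuron and sensory neuron (12), neural crest (12), oligodendrocyte and astrocyte (9), mesoderm, endothelium and fibroblast (12), epithelial (11) and pluripotency (12). Lists overlap, as when cadherins are also phrenic genes.

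Each of the 24 lists was tested in the 27 comparisons with YFP by limma's camera with a preset correlation of 0.01 between genes, adjusted over all 648 tests. Of these tests, 112 passed, and 14 of the 112 also passed with the correlation estimated from the data. Induced genes stayed in their lists. List members were also counted after adjustment over the list alone. Over-representation of the phrenic list among called genes, the measure named in the series description, was tested with Fisher's exact test, one-sided, against all 19938 genes and adjusted over 27 comparisons. Agreement between comparisons was described only for pairs that share no array. In groups of 4 arrays, named genes were examined for an outlying array with Dixon's ratio (critical value 0.829).

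Alternatives were the model without batch terms, a replicate block in place of the batch, CD2 and CD14 arrays fitted separately, arrays of 1 batch only, the parental lines pooled with YFP as controls, and genes left out unless above the median of all values, 8.21, on at least 2 arrays. Others were quantile normalization applied once more, the mean of all clusters of a gene, an estimated correlation for list tests, and each array left out in turn. Leaving out 6 of the 9 batch 4 arrays, or all 9, was chosen after seeing the data.

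The procedure was tested on simulated data with 200 changed genes among the 19938. At log2 changes of 0.5, 1 and 2 it recovered 62.7%, 100% and 100% of them for Pou3f1 in CD2 cells (4 false calls). For NERT 30 it was 35.8%, 89.6% and 100% (9) and for Hoxc6 in CD2 cells 14.9%, 70.1% and 97% (6). Relabelled real H4 and YFP arrays called up to 2526 genes, so false calls may be more. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.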

Results

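Motor neurons were derived from mouse embryonic stem cells to screen factors for their ability to induce genes of phrenic motor neurons, the cervical neurons that drive the diaphragm. Embryoid bodies received retinoic acid and a Smoothened agonist on day 2, which steer cells to a ventral spinal fate. On day 5 they were dissociated and sorted magnetically for a CD2 or a CD14 reporter, and a transgene was induced with doxycycline during 30 h of culture on matrigel. The 68 arrays fell into 31 groups, with 4 arrays each for YFP in CD2 cells, YFP in CD14 cells and Pou3f1 in CD2 cells. The H4 line had 3 arrays, the E3 line 1, and the other 26 groups 2 each. Median log2 values were 7.57 to 7.84 in batches 1 to 7 and 7.08 to 7.09 in batch 0. The names H4, E3 and NERT are used as the labels give them.

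Hox genes, which set position along the spinal cord, differed between CD2 arrays in a way that the lines did not explain. Hoxa5 read 12.14 to 12.75 in 6 of the 9 batch 4 arrays (1 of Hoxa5, 1 of Chd5, 2 of Pou3f1, 1 of H4 and 1 of Arid5b). It read 9.62 to 9.90 in the other 3 batch 4 arrays (1 of Hey1 and 2 of Notch1ICD 10) and 9.06 to 9.97 in the 4 YFP arrays. Hoxc5 read 12.14 to 12.50 in the same 6 arrays and 8.02 to 10.24 in the other 3, and Hoxb5 11.95 to 12.44 against 9.76 to 10.37.

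**Figure D1:**
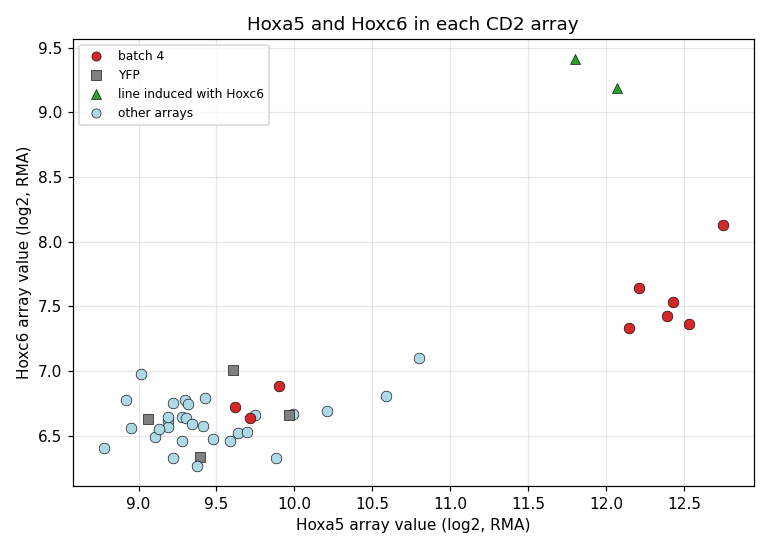
Hoxa5 (x axis) against Hoxc6 (y axis) in each CD2 array, as log2 values, with batch 4 arrays in red, YFP arrays as grey squares, the Hoxc6 line as green triangles and other arrays in light blue. In 6 batch 4 arrays Hoxa5 lay between 12.14 and 12.75 while Hoxc6 stayed between 7.33 and 8.12, below the 9.19 and 9.41 of the Hoxc6 line.

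The induced gene itself was examined first, in 28 pairs of gene and line. It rose in 15 pairs, fell in none, and did not pass limma's test in 13. Large rises were those of Lhx3, a LIM homeodomain factor of early motor neurons, by 3.89 ± 0.28 with Pou3f1 in CD14 cells and 3.31 ± 0.40 alone in CD2 cells, and of Hoxc6, by 3.50 ± 0.19 and 3.03 ± 0.25 (n = 2 each, adjusted p = 1.32e-12, 2.02e-06, 2.63e-16 and 3.85e-10). Klf5 rose by 3.27 ± 0.13, Vwc2 by 2.81 ± 0.12, Hey1 by 2.76 ± 0.25, Notch1 in the Notch1ICD 30 line by 1.57 ± 0.32 and Zic1 by 1.17 ± 0.20. Pou3f1 rose by 1.09 ± 0.15 in CD2 cells (n = 4, adjusted p = 9.84e-06) and by 0.70 to 1.84 in the combined CD14 lines. Alone in CD14 cells Pou3f1 was at 0.45 ± 0.19 (adjusted p = 0.583). In the Flag-tagged line it was at 0.48 ± 0.19 (adjusted p = 0.182). Also short of the threshold were Hoxa5 alone in CD2 cells (1.17 ± 0.40, adjusted p = 0.323), Notch1 in Notch1ICD 10 (0.57 ± 0.35), and Lhx3 in DNLhx3 (0.33 ± 0.26) and in Pou3f1+DNLhx3 (0.60 ± 0.28). The same held for Tox (0.54 ± 0.23), Chd5 (0.40 ± 0.11), Btbd3 (0.18 ± 0.16), Arid5b (0.10 ± 0.22), Zbtb7c (-0.05 ± 0.16), Klf6 (-0.30 ± 0.14) and Sfmbt2 (-0.41 ± 0.23). Zic1 lost its call without the batch 5 Zic1 array (adjusted p = 0.0751), and Pou3f1 in Pou3f1+DNLhx3 without replicate 1 of that line (0.0594). Without the 6 arrays, Hoxa5 passed in the Hoxa5 line (1.89, adjusted p = 0.0422) and Lhx3 in Pou3f1+DNLhx3 (0.60, adjusted p = 0.017). Which part of each transcript a transgene carried is not given in the sources used here, so a probe set may lie outside it.

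**Figure D2:**
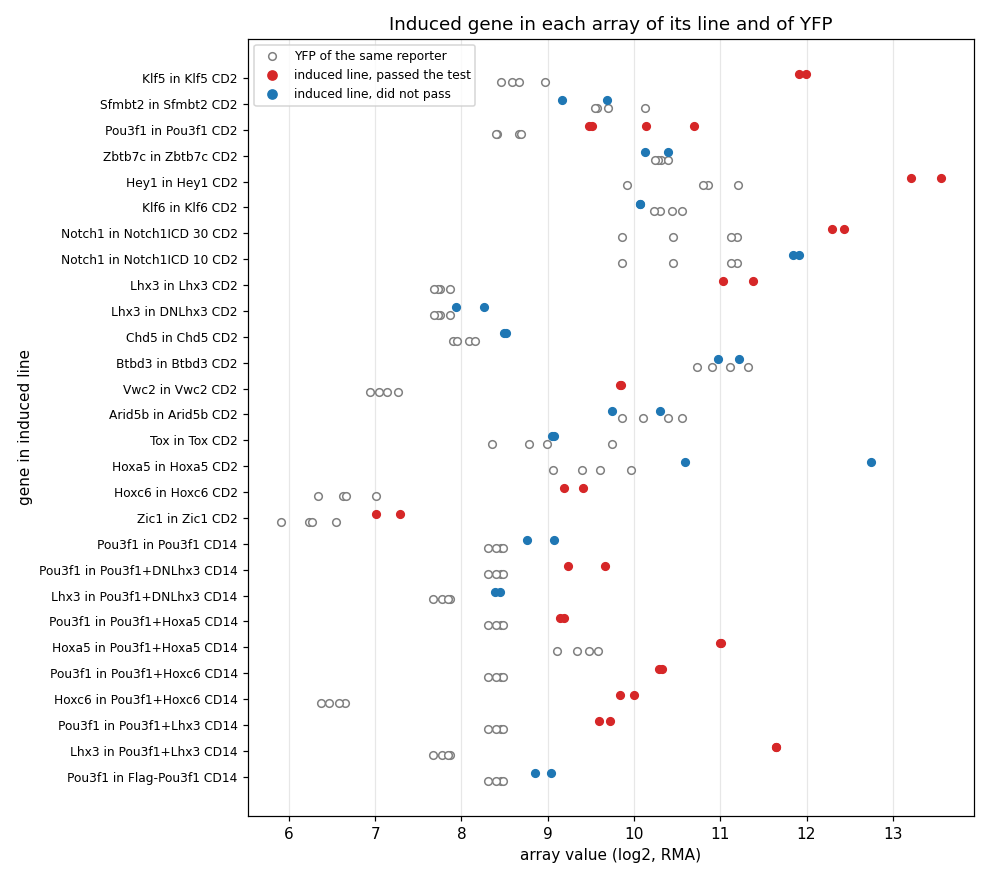
Array values (x axis, log2) of the induced gene in each of 28 gene and line pairs (y axis), with arrays of the line in red where the gene passed the test and in blue where it did not, and YFP arrays of the same reporter as open grey circles. The 2 Klf5 arrays lay at 11.92 and 11.99, above the YFP arrays at 8.46 to 8.97, whereas the 2 Klf6 arrays lay at 10.07, below the YFP arrays at 10.23 to 10.56.

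Pou3f1, a POU-domain factor of phrenic motor neurons, raised some cadherin genes, 5 of 29, in CD2 cells (n = 4 against 4 YFP arrays). Cdh9, a type II cadherin, rose 13.5-fold (3.76 ± 0.49, adjusted p = 4.83e-06), and Cdh10 rose 4.05-fold (2.02 ± 0.16, adjusted p = 2.45e-10). Pcdh10 rose by 1.17 ± 0.15 (adjusted p = 5.2e-06). Other rises were those of Inpp4b (2.07 ± 0.22), Tmem207 (2.05 ± 0.21) and Mro (1.87 ± 0.16). Lmo3 (1.86 ± 0.34) and C1ql4 (1.74 ± 0.22) rose as well, all with adjusted p from 1.02e-09 to 0.000875. Sst, which encodes somatostatin, fell by 2.11 ± 0.27 and the ventral homeobox gene Nkx2-9 fell by 2.05 ± 0.35. Th, tyrosine hydroxylase, fell by 1.64 ± 0.22 (adjusted p from 3.93e-06 to 0.000334). Mnx1, a motor neuron identity factor, rose by 0.70 ± 0.14 (adjusted p = 0.00215), while Isl1 was at 0.14 ± 0.12 (adjusted p = 0.696), and Hoxa5 (0.38 ± 0.29), Ptn (0.33 ± 0.22) and Alcam (0.07 ± 0.28) did not pass.

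The size of the cadherin rise differed between batches. In batches 1 and 2 Cdh9 read 11.33 and 11.12 in the Pou3f1 arrays and 5.84 and 5.73 in the YFP arrays of the same batch, differences of 5.48 and 5.39. In the 2 batch 4 Pou3f1 arrays, which had no YFP array in their batch, Cdh9 read 7.09 and 7.17. Cdh10 differed by 2.38 and 2.26 within batches 1 and 2, and Pcdh10 by 0.83 and 1.54.

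In this comparison 417 genes passed, 260 higher and 157 lower, and 1 left-out array moved the count from 185 (without the Pou3f1 array of batch 1) to 665 (without YFP replicate 1 of batch 3). Fitted with CD2 arrays only, 134 passed. From the 12 phrenic genes, 5 rose (Pou3f1, Pcdh10, Cdh9, Cdh10 and Negr1) and 0 fell, with 6 higher and 1 lower adjusted over the list alone (below, within the list) (limma's camera, adjusted p = 7.69e-08, and 0.0203 with an estimated correlation between genes, below with estimation). Among 29 cadherins and protocadherins, 5 rose, with 7 higher and 2 lower within the list (adjusted p = 0.0193, and 0.325 with estimation). The lateral motor column list had 2 higher and 1 lower of 10, and 4 and 1 within the list, and was not called (adjusted p = 0.0833). Of 17 cell cycle genes, 0 changed by limma in either adjustment, yet the list was called lower (median -0.57, adjusted p = 5.71e-07, and 0.658 with estimation), and the list mean ran from 9.27 to 10.73 over the YFP arrays alone. Of the 30 called genes that the naming rule took, 20 kept their call without any 1 array. Without the batch 2 YFP array, Actc1 (adjusted p = 0.127), Lhx1 (0.101), Nkx2-2 (0.16), Slit1 (0.178) and Ntn1 (0.348) lost it, and without the batch 1 YFP array Eya1 (0.115) and Zeb2 (0.253) did. Cartpt (0.238) and Negr1 (0.0674) lost it without the batch 1 Pou3f1 array and Cdh12 (0.179) without the batch 2 Pou3f1 array. Without the 6 batch 4 arrays Lhx1 (0.67, adjusted p = 0.368) and Actc1 (-1.51, 0.061) lost it, and Ptn passed (0.63, 0.00798).

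Pou3f1 in CD14 cells (n = 2 against 4) raised a set that Cdh9 also led, at 3.73 ± 0.62 (adjusted p = 0.000887). Tmem207 rose by 2.73 ± 0.26, Nr0b1 by 2.14 ± 0.27, Inpp4b by 2.04 ± 0.27, Mro by 1.76 ± 0.21, Pcp4l1 by 1.57 ± 0.19, Mast4 by 1.47 ± 0.17 and Cdh10 by 1.42 ± 0.21 (adjusted p from 3.87e-08 to 7.48e-05). These 8 genes kept their call without any 1 array. Pcdh10 was at 0.75 ± 0.19 (adjusted p = 0.0906), and passed with CD14 arrays fitted apart (4.06e-05), in batch 6 arrays alone (0.00108) and without batch terms (1.01, 0.00311). Mnx1 was at -0.29 ± 0.17 and Isl1 at -0.02 ± 0.15. The other 11 named genes lost their call without some array. Lmo3 (1.84 ± 0.42), Epha5 (1.26 ± 0.27), Foxp1 (1.01 ± 0.23), Il1rap (1.49 ± 0.26) and Crabp1 (-0.96 ± 0.22) did so without YFP replicate 2 of batch 6 (adjusted p = 0.683, 0.389, 0.427, 0.0724 and 0.628). Vstm2a (1.75 ± 0.39) and Adgrg6 (-1.53 ± 0.35) did so without YFP replicate 1 of batch 6 (0.434 and 0.424), and S100a11 (-1.27 ± 0.29) without Pou3f1 replicate 1 (0.428). Pcdh19 (1.33 ± 0.26), Robo1 (0.80 ± 0.16) and Rasgrp1 (-0.99 ± 0.21) did so without Pou3f1 replicate 2 (0.271, 0.229 and 0.406).

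Here 61 genes passed, 49 higher and 12 lower, with 16 (without Pou3f1 replicate 2) to 58 (without YFP replicate 1 of batch 7) when 1 array was left out, 302 in batch 6 arrays alone and 133 without the 6 batch 4 arrays. The phrenic list had 2 of 12 genes higher, 3 within the list (adjusted p = 1.78e-06, and 0.0447 with estimation). Of 29 cadherins 3 rose, 6 within the list (adjusted p = 0.000368, and 0.0644 with estimation). The lateral motor column list (2 of 10 higher, 3 within the list) and axon guidance list (3 of 41 higher, 6 within the list) were called higher (adjusted p = 0.0107 and 0.0163, and 0.174 and 0.431 with estimation). Across genes, which are not independent replicates, the CD2 and CD14 effects of Pou3f1 correlated at r = 0.367 (rho = 0.158) with no array shared. Of called genes, 35 rose in both where 0.639 would be met by chance, 3 fell in both, and 0 were called in opposite directions. The difference of the effects, CD14 minus CD2, was called for 2 of 19938 genes, Nr0b1 and Pou3f4.

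The Flag-tagged Pou3f1 line in CD14 cells (n = 2) raised Tmem207 by 2.95 ± 0.26, Cdh9 by 2.83 ± 0.62, Inpp4b by 2.01 ± 0.27 and Cdh10 by 1.47 ± 0.21 over YFP (adjusted p = 4.59e-09, 0.00861, 3.02e-05 and 5.2e-05). Bmp7, a BMP ligand, fell by 1.28 ± 0.20 (adjusted p = 0.000264). Cdh9 read 7.80 and 9.60 in these 2 arrays and lost its call without replicate 2 (adjusted p = 0.273), as did Pcdh10 (0.85 ± 0.19) without YFP replicate 1 of batch 6 (0.186). In all, 256 genes were higher and 230 lower, from 40 (without YFP replicate 1 of batch 6) to 435 (without YFP replicate 1 of batch 7), and 2227 passed in batch 6 arrays alone. Phrenic genes called were 3 higher, with 5 higher and 2 lower within the list (adjusted p = 0.0208, and 0.491 with estimation). Against untagged Pou3f1, Pou3f1 itself was at 0.03 ± 0.19 (adjusted p = 0.96), whereas 162 genes were higher and 278 lower. Malat1, a nuclear noncoding RNA, was higher by 1.72 ± 0.37 (adjusted p = 0.00768) and Snord73b, a small nucleolar RNA, by 1.58 ± 0.27 (adjusted p = 0.000759). Usp17ld fell by 1.80 ± 0.20 (adjusted p = 2.68e-06). Of the 6 genes named there, only Usp17ld kept its call without any 1 array, with Malat1 at 0.157 without Pou3f1 replicate 2 and Snord73b at 0.0688 without Flag replicate 2. That count of 440 was 53 without Pou3f1 replicate 2 and 115 without Flag replicate 1. It was 2351 in batch 6 arrays alone (1262 higher and 1089 lower) and 0 by limma without batch terms (3261 at unadjusted p under 0.05 with them).

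Over-representation of the phrenic list among called genes passed in 9 of the 27 comparisons with YFP (Fisher's exact test, one-sided). The most members, 10 of 12, were called in Pou3f1+Hoxc6 (adjusted p = 5e-08), with 7 in Pou3f1+Hoxa5 (2.05e-05) and 5 in Pou3f1 in CD2 cells (2.47e-05). There were 5 in Pou3f1+DNLhx3 (0.000429), 2 in Pou3f1 in CD14 cells (0.00322), and 3 each in Hoxc6 in CD2 cells and in Flag-Pou3f1 (both 0.0104). With the induced gene left out of the list these 7 values became 4.62e-07, 0.00126, 0.000741, 0.00361, 0.00336, 0.00926 and 0.00922. Also passing were Notch1ICD 10 (3 members) and Notch1ICD 30 (4 members), both at 0.014, where members went both ways. In Notch1ICD 10 Cdh10 rose, and Hoxa5 and Hoxc5 had fitted falls that turned to 0.15 and 1.61 without the 6 batch 4 arrays. In Notch1ICD 30 Pou3f1, Ptn and Cdh10 rose and Cdh6 fell. Without the 6 batch 4 arrays Notch1ICD 10 did not pass but Hoxa5 alone and Pou3f1+Lhx3 did. With dim genes left out Hoxc6, Flag-Pou3f1 and Notch1ICD 30 did not. In 14 comparisons no member was called by limma. Alcam and Cdh6 rose in 0 of the 27. Of the 10 in Pou3f1+Hoxc6, parental H4 read Pou3f1, Hoxa5, Hoxc5, Hoxc4, Ptn and Tshz1, but not the others, highest in batch 4.

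**Figure D3:**
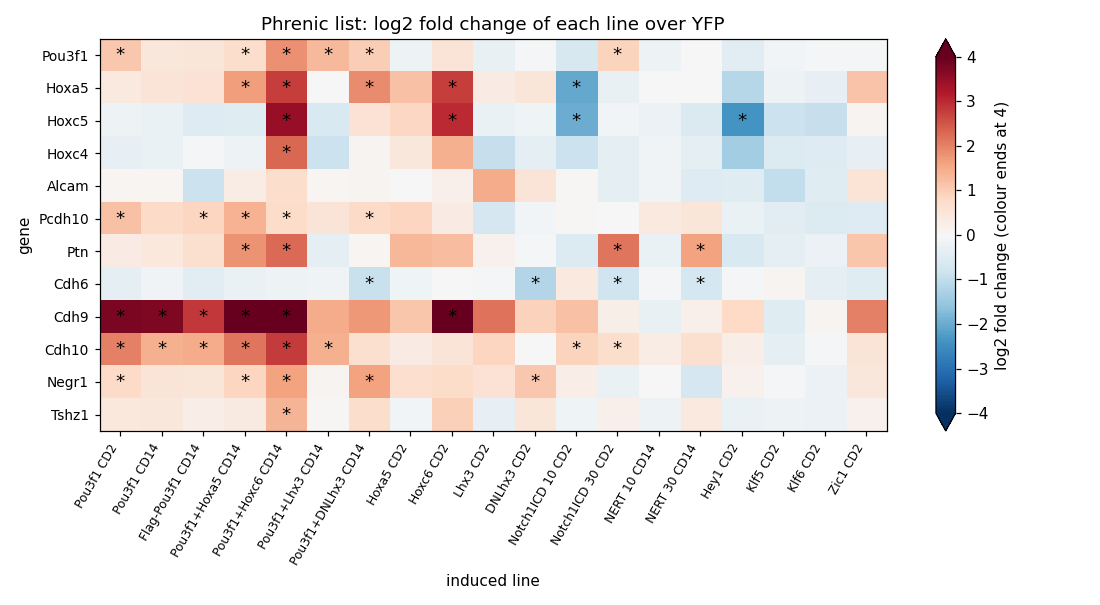
Log2 fold change over YFP (colour, ending at 4) of the 12 phrenic genes (y axis) in 19 lines (x axis), with a star where the adjusted p was under 0.05. Starred rises gather in Pou3f1+Hoxc6 (10 genes), Pou3f1+Hoxa5 (7) and Pou3f1 in CD2 cells (5).

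Adding Hoxa5, a cervical Hox gene, to Pou3f1 in CD14 cells (n = 2) was the test of the pair of factors. Ptn, which encodes the secreted growth factor pleiotrophin, rose 3.48-fold (1.80 ± 0.28, adjusted p = 6.63e-05). Cdh9 rose by 4.29 ± 0.62, Cdh10 by 2.14 ± 0.21 and Pcdh10 by 1.38 ± 0.19 (adjusted p = 2.09e-05, 7.71e-09 and 1.41e-05). Tmem207 (3.18 ± 0.26), Vstm2a (3.09 ± 0.39), Inpp4b (2.62 ± 0.27), Epha5 (2.59 ± 0.27) and Mecom (2.43 ± 0.43) also rose, with adjusted p from 4.7e-10 to 0.000362. Among transcription factors, Eya1 fell by 2.86 ± 0.39, Ebf2 fell by 2.79 ± 0.41 and Zeb2 fell by 2.43 ± 0.30. Ntm fell by 2.06 ± 0.33 and Ret fell by 1.31 ± 0.16 (adjusted p from 1.31e-06 to 8.96e-05). These genes kept their call without any 1 array. Hoxa5 (1.66 ± 0.36) lost it without YFP replicate 2 of batch 6 (adjusted p = 0.0805), as did Mnx1 (0.73 ± 0.17, adjusted p = 0.0908), and Pou3f1 (0.70 ± 0.19) without Pou3f1+Hoxa5 replicate 2 (0.146). Isl1 was at 0.36 ± 0.15 (adjusted p = 0.16) and Alcam at 0.31 ± 0.35.

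Against YFP 617 genes were higher and 563 lower, with 278 (without YFP replicate 1 of batch 6) to 1116 (without YFP replicate 1 of batch 7) when 1 array was left out and 2037 higher and 1349 lower in batch 6 arrays alone. With quantile normalization once more the balance turned, to 539 and 692. Of the phrenic list 7 rose, also within the list, and 0 fell (adjusted p = 1.99e-07, and 0.0228 with estimation). Of 14 neurotrophic and neuropeptide genes 1 rose and 4 fell, 1 and 6 within the list, among them Sst (-1.76 ± 0.34) and Gal (-1.11 ± 0.32) (adjusted p = 0.0438, and 0.289 with estimation). Sst lost its call without Pou3f1+Hoxa5 replicate 3 (0.073) and Gal without YFP replicate 1 of batch 6 (0.262). The Hox paralogues 1 to 5 were not called (1 higher and 3 lower of 14, also within the list, adjusted p = 0.103), although Hoxb2 fell by 0.81 ± 0.19 (0.12 without Pou3f1+Hoxa5 replicate 3). Against Pou3f1 alone, 253 genes were higher and 434 lower (103 to 252 genes in all without Pou3f1+Hoxa5 replicate 3 or 2). This balance turned too, to 1441 and 1244 in batch 6 arrays alone and 2059 and 1605 with CD14 arrays fitted apart. Mnx1 rose by 1.02 ± 0.17 and Zeb2 fell by 1.92 ± 0.30 (adjusted p = 0.0003 and 0.000113), and Pappa2 fell by 2.23 ± 0.31 (2e-05). Ptn rose by 1.38 ± 0.28 (0.00274, and 0.0545 without Pou3f1+Hoxa5 replicate 3), and Hoxa5 was at 1.14 ± 0.36 (0.0685, and 0.00275 without the 6 batch 4 arrays). Beside these changes the 51 small nucleolar RNA genes had a median of 0.363 over Pou3f1 alone (4 called higher), Malat1 read 11.96 and 11.97 against 10.36 and 10.67, and Mki67, a proliferation gene, 8.20 and 8.57 against 9.31 and 9.53.

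Hoxa5 alone in CD2 cells (n = 2, batches 4 and 5) changed 0 genes by limma, with 2071 at unadjusted p under 0.05. Ptn was at 1.33 ± 0.31 (adjusted p = 0.147) and Pcdh10 at 0.86 ± 0.22 (adjusted p = 0.165). The phrenic list was called higher (0 of 12, and 4 higher within the list, adjusted p = 0.000595, and 0.216 with estimation), and the Hox paralogues 1 to 5 likewise (0 of 14 in both adjustments, adjusted p = 0.00718, and 0.764 with estimation). Without the 6 batch 4 arrays, of which 1 is of this line, 85 genes passed and Ptn rose by 1.98 (adjusted p = 0.000144). Ptn also passed without the Hoxa5 array of batch 4 alone (2.19, adjusted p = 0.0186), when 36 genes did.

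Pou3f1+Hoxc6 in CD14 cells (n = 2) gave the highest count of any comparison with YFP, 957 genes higher and 833 lower (893 and 998 with quantile normalization once more). These 2 arrays, like those of Pou3f1+Hoxa5 and Flag-Pou3f1, read Malat1 at 11.96 to 12.25, against 10.36 to 10.91 in the other 7 CD14 arrays of batch 6. Cdh9 rose 51.8-fold (5.70 ± 0.62, adjusted p = 2.21e-08) and Aldh1a2, the retinoic acid-synthesizing enzyme that marks brachial motor neurons, rose 38.2-fold (5.26 ± 0.46, adjusted p = 1.52e-10). Cdh7 (3.65 ± 0.27), Cdh20 (2.86 ± 0.32), Cdh10 (2.79 ± 0.21), Ptn (2.25 ± 0.28) and Foxp1, the limb motor column factor (1.88 ± 0.23), rose with adjusted p from 1.76e-12 to 3.43e-07. Hoxc5 (3.48 ± 0.54), Hoxa5 (2.77 ± 0.36) and Hoxc4 (2.29 ± 0.35) rose too. Hoxd3 fell by 1.72 ± 0.34 (adjusted p from 7.47e-07 to 0.000722). The Hox 1 to 5 list was not called. Sst fell 17.7-fold (-4.14 ± 0.34) and Eya1 fell by 4.00 ± 0.39. Cartpt fell by 3.76 ± 0.51, Zeb2 fell by 3.59 ± 0.30 and Isl2 fell by 1.44 ± 0.23 (adjusted p from 3.18e-11 to 2.52e-05). Of 24 named genes 20 kept their call without any 1 array. Pcdh10 (0.73 ± 0.19), Isl1 (0.52 ± 0.15) and Lhx3 (1.00 ± 0.28) lost it without YFP replicate 1 of batch 6 (adjusted p = 0.113, 0.172 and 0.14), and Lmo3 (1.85 ± 0.42) without YFP replicate 2 of batch 6 (0.0809).

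In the phrenic list 10 of 12 genes rose, also within the list, all but Alcam and Cdh6 (adjusted p = 1.68e-17, and 0.00029 with estimation). Of 29 cadherins 9 rose and 4 fell, 9 and 5 within the list, and this list was not called (adjusted p = 0.105). The Hox paralogues 6 to 13 were called higher (3 of 23, induced Hoxc6 included, also within the list, adjusted p = 0.00886, and 0.626 with estimation). Against Pou3f1 alone, 931 genes were higher and 857 lower, a balance that turned to 683 and 911 with quantile normalization once more and 596 and 898 with dim genes left out. Among them Aldh1a2 rose by 5.76 ± 0.46, Hoxc5 by 3.75 ± 0.54, Hoxa5 by 2.25 ± 0.36 and Pou3f1 itself by 1.39 ± 0.19 (adjusted p from 2.96e-11 to 4.11e-05), and Sst fell by 3.19 ± 0.34. The 51 small nucleolar RNA genes had a median of 0.427 there, with 15 called higher. Counts with 1 array left out ran from 715 (without YFP replicate 1 of batch 6) to 1716 (without YFP replicate 1 of batch 7) against YFP and from 573 (without Pou3f1+Hoxc6 replicate 2) to 914 (without Pou3f1 replicate 1) against Pou3f1. In batch 6 arrays alone 2463 were higher and 1652 lower against YFP, and 2912 and 1814 against Pou3f1. Mki67 read 8.51 and 8.49 in these 2 arrays and 9.31 and 9.53 in Pou3f1.

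Hoxc6 alone in CD2 cells (n = 2, both in batch 5, which had no YFP array) raised Aldh1a2 35.9-fold (5.17 ± 0.63, adjusted p = 1.7e-06). Cdh9 rose by 4.11 ± 0.84, Cdh7 by 3.82 ± 0.36, Foxp1 by 2.91 ± 0.31, Hoxa5 by 2.75 ± 0.49 and Cdh20 by 2.49 ± 0.44 (adjusted p from 8.94e-09 to 0.00362). Cartpt fell by 3.14 ± 0.69, Eya1 fell by 2.64 ± 0.52 and Zeb2 fell by 2.13 ± 0.40 (adjusted p = 0.00722, 0.00277 and 0.00183). Without Hoxc6 replicate 2, Epha4 (1.43 ± 0.30), Gfra1 (1.62 ± 0.34), Ccdc3 (-2.58 ± 0.56) and Isl2 (-1.25 ± 0.31) lost their call (adjusted p = 0.0762, 0.0556, 0.0567 and 0.163), and without replicate 1 Hoxc5 (2.99 ± 0.73) did (0.0664). Without the 6 batch 4 arrays Cdh20 was at 1.59 (adjusted p = 0.0817), Cdh12 at 1.16 (0.29) and Gfra1 at 0.55 (0.411). In all 240 genes were higher and 228 lower, and 138 passed with CD2 arrays only. Of the phrenic list 3 rose, 7 within the list (adjusted p = 1.36e-08, and 0.0178 with estimation). Of the 10 lateral motor column genes 3 rose, Aldh1a2, Foxp1 and Epha4, and 4 within the list (adjusted p = 0.000147, and 0.0203 with estimation). Among 29 cadherins 6 rose and 1 fell, 7 and 4 within the list, and the list was called higher although its median was -0.02 and its mean 0.42 (adjusted p = 0.015, and 0.289 with estimation). Of 14 Hox paralogues 1 to 5, 2 rose, 5 within the list (adjusted p = 3.13e-05, and 0.589 with estimation).

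Lhx3 in CD2 cells (n = 2) lay, like Zic1, in batches 5 and 6, without CD2 YFP arrays. It raised Slitrk6 19.4-fold (4.28 ± 0.37, adjusted p = 1.24e-09). Rpp25 rose by 3.21 ± 0.38, Cbln1 by 2.99 ± 0.43 and Hcrtr2 by 2.63 ± 0.29. Htr1a fell by 2.39 ± 0.29 (adjusted p = 1.41e-06, 4.18e-05, 3.81e-07 and 2.45e-06 in that order). With Lhx3 these 6 of 25 named genes kept their call without any 1 Lhx3 or YFP array. The other 19 lost it without the batch 5 Lhx3 array, among them Frzb (3.03 ± 0.40, adjusted p = 0.16 without it), Tac1 (3.16 ± 0.64, 0.183), Epha4 (2.01 ± 0.32, 0.274), Sim1, a median motor column factor (1.28 ± 0.23, 0.626), and Chrm2 (-1.95 ± 0.38, 0.572). Isl1 was at -0.61 ± 0.21 (adjusted p = 0.087) and Mnx1 at 0.53 ± 0.24 (adjusted p = 0.187). Without the 6 batch 4 arrays both passed (-0.98 and 0.92, adjusted p = 0.0147 and 0.0371), and Tac1 did not (2.39, 0.0574). Counts were 333 higher and 426 lower, from 25 (without the batch 5 Lhx3 array) to 1343 (without the batch 6 Lhx3 array). The 4 median motor column genes were called higher (1 higher, and 2 within the list, adjusted p = 0.0139, and 0.413 with estimation). The axon guidance list (7 higher and 1 lower of 41, 8 and 3 within the list) was called higher (adjusted p = 0.028, and 0.491 with estimation). The cell cycle list was too (0 of 17 by limma in both adjustments, median 0.69, adjusted p = 0.00413, and 0.826 with estimation). The generic motor neuron list was not called (1 higher and 2 lower of 13, 2 and 3 within the list, adjusted p = 0.79).

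Pou3f1+Lhx3 in CD14 cells (n = 2) raised Tmem207 by 4.44 ± 0.26, C1ql4 by 3.37 ± 0.27, Tac1 by 2.70 ± 0.45, Nkx6-2 by 2.37 ± 0.20, Cdh7 by 2.30 ± 0.27 and Cdh10 by 1.43 ± 0.21 (adjusted p from 7.08e-15 to 7.04e-05). Sst fell by 4.05 ± 0.34, Ccdc3 fell by 2.68 ± 0.41 and Shisa6 fell by 2.67 ± 0.30 (adjusted p = 1.03e-10, 2.51e-05 and 7.39e-08). Mnx1 rose by 0.90 ± 0.17 (adjusted p = 0.000451). Of the BMP and TGF-beta response list, called lower, 5 of 14 genes fell, or 7 within the list, with 0 higher (adjusted p = 1.93e-06, and 0.0223 with estimation). Bmp4 fell by 2.30 ± 0.37, and Id3 (-1.65 ± 0.37), Bmp2 (-1.28 ± 0.26) and Bambi (-0.54 ± 0.16) lost their call without YFP replicate 2 of batch 7 (adjusted p = 0.0915, 0.108 and 0.318). Without batch terms all 4 lost it (-1.07, -0.51, -0.81 and -0.33, adjusted p = 0.403, 0.686, 0.185 and 0.379), while the list stayed called. There were 441 genes higher and 344 lower, 354 (without that YFP array) to 749 (without YFP replicate 1 of batch 6) with 1 array left out, and 1568 in batch 7 arrays alone. Of the phrenic list 2 rose, 3 within the list, and the list was not called (adjusted p = 0.096). Against Pou3f1 alone 70 genes were higher and 30 lower (52 without Pou3f1 replicate 2, and 166 without the 6 batch 4 arrays). Tafa4 rose by 2.82 ± 0.22 and Sst fell by 3.10 ± 0.49 (adjusted p = 4.69e-11 and 0.000323). Mnx1 rose by 1.19 ± 0.24 (0.0652 without Pou3f1 replicate 1). These lines lay in different batches. Bmp4, lower by 2.43 ± 0.53, lost its call without Pou3f1+Lhx3 replicate 4 (adjusted p = 0.129) and was at 0.05 without batch terms.

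DNLhx3, by its label a dominant-negative form of Lhx3, lowered motor neuron genes in CD2 cells (n = 2, batch 3). Of 13 generic motor neuron genes 8 fell and 0 rose, with 12 lower within the list (adjusted p = 7.09e-16, and 0.00201 with estimation). Isl1 fell by 0.79 ± 0.14, Chat, the acetylcholine-synthesizing enzyme, fell by 0.94 ± 0.13 and the choline transporter gene Slc5a7 fell by 1.14 ± 0.21 (adjusted p = 0.000164, 5.01e-06 and 0.000341), while Mnx1 was at -0.21 ± 0.16 (adjusted p = 0.555). Rpp25 rose 29.9-fold (4.90 ± 0.25, adjusted p = 1.99e-17) and Lhx1, a LIM homeodomain factor of lateral motor neurons and interneurons, rose 17.1-fold (4.10 ± 0.36, adjusted p = 1.87e-10). Lamp5 (3.35 ± 0.16), Vstm2a (3.27 ± 0.36) and Cbln4 (2.98 ± 0.18) rose too. Sema5a (2.22 ± 0.25), Dlx1 (2.13 ± 0.15) and Slc17a6 (1.64 ± 0.22) also rose (adjusted p from 1.35e-17 to 3.69e-06). Sema3d fell by 2.09 ± 0.28, Htr1a fell by 1.96 ± 0.19 and Dlc1 fell by 1.94 ± 0.14. Zeb2 fell by 1.87 ± 0.28, Unc5c fell by 1.83 ± 0.21 and Slit2 fell by 1.11 ± 0.09 (adjusted p from 4.75e-13 to 1.56e-05). There were 399 genes higher and 416 lower, 333 (without DNLhx3 replicate 2) to 1784 (without YFP replicate 1 of batch 3), and 263 in batch 3 arrays alone. Among 41 axon guidance genes 4 rose and 8 fell, 6 and 14 within the list (adjusted p = 0.00718, and 0.325 with estimation). The phrenic list was not called (1 higher and 1 lower in both adjustments, adjusted p = 0.68), with a median of -0.04 and a mean of 0.12. Of 29 named genes 23 kept their call without any 1 array. Chodl (-1.15 ± 0.34), Mecom (-1.35 ± 0.40), Mgat4c (-1.78 ± 0.47), Nkx6-1 (0.74 ± 0.20) and Sstr2 (-1.86 ± 0.42) lost it without DNLhx3 replicate 2 (adjusted p = 0.496, 0.437, 0.294, 0.206 and 0.0948), and Lhx4 (1.18 ± 0.25) without replicate 1 (0.0529).

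Pou3f1+DNLhx3 in CD14 cells (n = 2) lowered 11 of 13 generic motor neuron genes and raised 0, also within the list (adjusted p = 5.37e-29, and 5.61e-05 with estimation). Ret fell by 2.41 ± 0.16, Chodl fell by 2.19 ± 0.36, Slc5a7 fell by 1.56 ± 0.22 and Isl1 fell by 1.03 ± 0.15 (adjusted p from 1.15e-13 to 5.39e-05). Mnx1 fell by 0.70 ± 0.17 (0.136 without YFP replicate 1 of batch 6). Rpp25 rose by 4.61 ± 0.26, Vstm2a by 4.35 ± 0.39, Lhx1 by 3.59 ± 0.38 and Sema5a by 2.37 ± 0.27. Sst fell by 3.43 ± 0.34, Sema3d fell by 3.41 ± 0.30 and Slit2 fell by 1.90 ± 0.10 (adjusted p from 1.23e-16 to 4.77e-08). Among phrenic genes Pou3f1, Hoxa5 (1.88 ± 0.36), Pcdh10 (0.78 ± 0.19, 0.115 without YFP replicate 1 of batch 6) and Negr1 (1.62 ± 0.21) rose and Cdh6 fell by 0.90 ± 0.16, with 7 higher and 1 lower within the list (adjusted p = 4.15e-05, and 0.105 with estimation). Called genes were 422 higher and 376 lower, 423 (without YFP replicate 2 of batch 6) to 768 (without YFP replicate 1 of batch 7) with 1 array left out, and 1667 in batch 6 arrays alone. Against Pou3f1 alone 189 were higher and 231 lower, and 192 to 289 without DNLhx3 replicate 1 or 2. Tmem207, which Pou3f1 alone had raised, fell by 2.95 ± 0.26 (adjusted p = 3.56e-10), and Isl1 fell by 1.01 ± 0.15 (adjusted p = 1.14e-05). Hoxa5 rose by 1.36 ± 0.36 (adjusted p = 0.0295, and 0.257 without Pou3f1 replicate 2). Without batch terms Hoxa5 lost both calls (1.85, adjusted p = 0.118 over YFP, and 1.36, 0.914 over Pou3f1).

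Notch1ICD, the active intracellular part of the Notch1 receptor, was induced in CD2 cells under a label with the number 30 (n = 2, batch 3). Notch target genes rose, Hey2 23.6-fold (4.56 ± 0.29, adjusted p = 6.76e-15), Nrarp by 2.83 ± 0.26, Heyl by 2.60 ± 0.16, Hes5 by 2.18 ± 0.17 and Hey1 by 1.59 ± 0.24 (adjusted p from 1.64e-15 to 9.35e-06). Of 12 Notch targets 8 rose and 0 fell, 9 higher within the list (adjusted p = 1.23e-18, and 0.000401 with estimation). Of 13 generic motor neuron genes 8 fell and 0 rose, 9 lower within the list (adjusted p = 6.03e-10, and 0.0203 with estimation), with Isl1 lower by 0.91 ± 0.14 and Isl2 by 1.24 ± 0.21 (adjusted p = 6.91e-06 and 7.55e-05). Mnx1 (-0.68 ± 0.16) and Slc5a7 (-0.88 ± 0.21) lost their call without Notch1ICD replicate 1 (adjusted p = 0.107 and 0.274). Calb1 had the largest rise, 56.0-fold (5.81 ± 0.23, adjusted p = 2.62e-21), and Ptges (4.83 ± 0.18), Fgf15 (4.05 ± 0.15) and Frzb (3.89 ± 0.26) rose too. Tal1 and Gata3, factors of V2b interneurons, rose by 2.89 ± 0.12 and 2.47 ± 0.17. The glial and progenitor factor Sox9 rose by 2.07 ± 0.27, Ptn by 2.15 ± 0.26 and Id1 by 2.31 ± 0.23 (adjusted p from 3.25e-21 to 2.99e-07). Nkx2-9 fell by 3.23 ± 0.41, Gabrg1 fell by 1.98 ± 0.31 and the neurofilament gene Nefm fell by 0.85 ± 0.11 (adjusted p from 2.09e-07 to 1.37e-05). Pou3f1 (0.88 ± 0.17), Cdh10 (0.71 ± 0.19), Dcn (-2.79 ± 0.69), Moxd1 (-1.82 ± 0.49), Nkx2-2 (-1.71 ± 0.37), Igfbp3 (-1.66 ± 0.41) and Eya1 (-1.58 ± 0.36) passed but not without Notch1ICD replicate 2 (adjusted p = 0.184, 0.218, 0.114, 0.28, 0.0921, 0.0759 and 0.0585).

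There were 705 genes higher and 505 lower, and 557 passed in batch 3 arrays alone. The neural progenitor list was called higher (1 of 16, and 4 higher and 1 lower within the list, adjusted p = 0.0152, and 0.671 with estimation). The ventral interneuron list was too (3 higher and 1 lower of 15, also within the list, adjusted p = 0.0249, and 0.51 with estimation), as was the cell cycle list (0 of 17 by limma in both adjustments, median 0.62, adjusted p = 0.000147, and 0.764 with estimation). The Notch ligands and proneural factors were not called (adjusted p = 0.0551), with Dll1, Dll3 and Jag2 lower, 3 of 13, or 1 higher and 5 lower within the list. Each of these 3 lost its call without Notch1ICD replicate 1 (adjusted p = 0.155, 0.232 and 0.459).

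NERT under the number 30 in CD14 cells (n = 2, batch 7) raised the same Notch targets, Hey2 21.0-fold (4.39 ± 0.31), Hes5 by 2.68 ± 0.19, Nrarp by 2.57 ± 0.28, Heyl by 2.39 ± 0.17 and Hey1 by 1.29 ± 0.26 (adjusted p from 8.75e-14 to 0.000985). Of the 12 targets 7 rose, 8 within the list (adjusted p = 7.09e-16, and 0.00129 with estimation). Of 13 generic motor neuron genes 9 fell, 12 within the list (adjusted p = 2.04e-10, and 0.0203 with estimation), among them Ret (-1.03 ± 0.16) and Slc18a3 (-0.75 ± 0.14). Isl1 (-0.72 ± 0.15) and Isl2 (-0.95 ± 0.23) lost their call without NERT 30 replicate 2 (adjusted p = 0.0585 and 0.144), and Mnx1 (-0.63 ± 0.17) without YFP replicate 1 of batch 7 (0.289). Calb1 rose by 5.33 ± 0.25, Rspo1 by 4.24 ± 0.13 and Qrfpr by 3.96 ± 0.18. Fgf15 rose by 3.61 ± 0.16, Ptges by 3.50 ± 0.19, Tal1 by 2.74 ± 0.12 and Gata3 by 1.75 ± 0.18. Ntrk2 rose by 2.36 ± 0.18, Sox9 by 2.09 ± 0.28, Id1 by 2.14 ± 0.25 and Ptn by 1.60 ± 0.28 (adjusted p from 7.12e-25 to 0.000154). Foxa1 fell by 1.91 ± 0.42, Foxa2 fell by 1.45 ± 0.36 and Shh fell by 1.43 ± 0.42, and each lost its call without batch terms (adjusted p = 0.102, 0.248 and 0.232) and without some array (0.127 without YFP replicate 2 of batch 7, 0.126 without NERT 30 replicate 2, and 0.338 without YFP replicate 2 of batch 7). Called genes were 581 higher and 357 lower, 371 (without NERT 30 replicate 2) to 885 (without YFP replicate 1 of batch 6), 2788 in batch 7 arrays alone and 1864 without batch terms. Across genes the effects of Notch1ICD 30 and NERT 30, which share no array, correlated at r = 0.66 (rho = 0.371). Of the called genes 366 rose and 137 fell in both, where 20.5 and 9.04 would be met by chance, and 0 went in opposite directions.

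**Figure D4:**
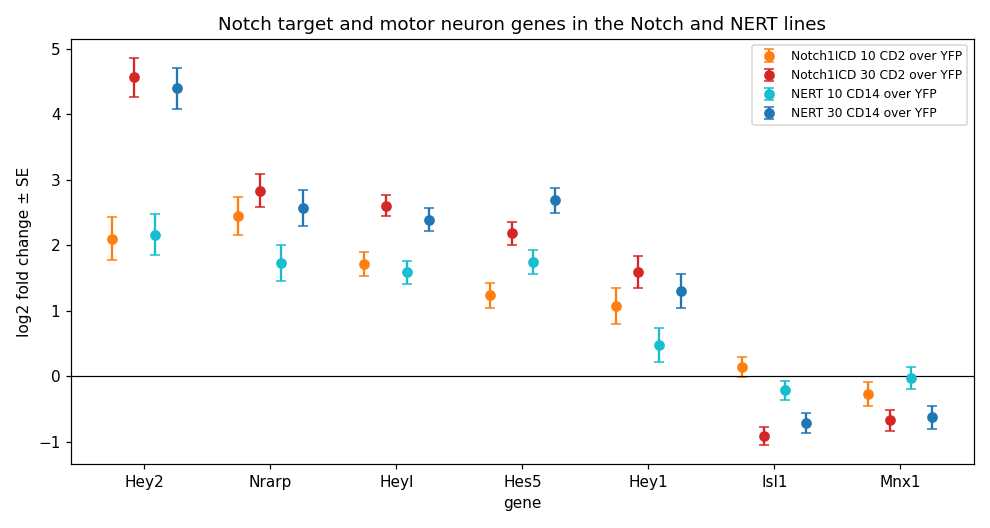
Log2 fold change over YFP (y axis) with its standard error (bars) for Hey2, Nrarp, Heyl, Hes5, Hey1, Isl1 and Mnx1 (x axis) in Notch1ICD 10 and 30 (CD2 cells) and NERT 10 and 30 (CD14 cells), 2 arrays each. Hey2 was at 2.10, 4.56, 2.16 and 4.39 in that order, and Isl1 at 0.14, -0.91, -0.22 and -0.72.

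Groups whose labels carry the number 10 were set beside those with 30, since in some Notch experiments the transgene was induced only for the last 10 of the 30 h. In NERT 10 (n = 2) Hey2 rose by 2.16 ± 0.31, Fam122b by 2.03 ± 0.18, Ptges by 1.95 ± 0.19, Hes5 by 1.74 ± 0.19, Nrarp by 1.72 ± 0.28, Heyl by 1.58 ± 0.17 and Efna1 by 1.38 ± 0.14 (adjusted p from 1.83e-09 to 0.000328), and kept their call without any 1 array. Isl1 was at -0.22 ± 0.15 and Mnx1 at -0.02 ± 0.17 (adjusted p = 0.711 and 0.984). Of the targets 4 of 12 rose, 5 within the list (adjusted p = 3.75e-13, and 0.00337 with estimation), and 78 genes were higher and 5 lower, 28 in all without YFP replicate 1 of batch 7. Tested directly, NERT 30 exceeded NERT 10 in Calb1 by 4.26 ± 0.25, Rspo1 by 3.93 ± 0.13 and Ptn by 1.86 ± 0.28 (adjusted p from 1.05e-23 to 1.78e-05). Fam122b fell by 1.76 ± 0.18 and Mgll fell by 1.58 ± 0.28 (adjusted p = 4.96e-09 and 0.000188). Hes5 was higher by 0.95 ± 0.19 (0.059 without NERT 10 replicate 1), and Isl1 (-0.50 ± 0.15) and Mnx1 (-0.61 ± 0.17) lower (0.439 and 0.386 without NERT 30 replicate 2). That comparison called 373 genes higher and 381 lower, 295 (without NERT 30 replicate 2) to 431 with 1 array left out.

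Notch1ICD 10 (n = 2, both in batch 4, which had no YFP array) raised Ptges by 3.96 ± 0.20, Hey2 by 2.10 ± 0.33, Heyl by 1.71 ± 0.18 and Hes5 by 1.23 ± 0.19 (adjusted p from 8.06e-17 to 8.64e-05). These 4 kept their call without any 1 array, without the 6 batch 4 arrays and without batch terms. Nrarp rose by 2.45 ± 0.29 (0.0877 without the 6 batch 4 arrays) and Hey1 by 1.07 ± 0.27 (0.519 without them). Of 12 Notch targets 6 rose, with 6 higher and 1 lower within the list (adjusted p = 4.14e-07, and 0.0551 with estimation). In the proneural list Neurod4 was at -2.60 ± 0.64, Neurod1 at -1.21 ± 0.27 and Neurog2 at -0.98 ± 0.28. The list was called lower (3 of 13, 5 within the list, adjusted p = 0.00396, and 0.242 with estimation). Without the 6 arrays it was at 0.311, with Neurod4 at adjusted p = 0.602, Neurod1 at 0.561 and Neurog2 at 0.965 (log2 change 0.09). The Hox paralogues 1 to 5 were called lower (8 of 14, 10 within the list, adjusted p = 3.18e-11, and 0.261 with estimation), and higher without the 6 arrays (adjusted p = 0.000867). Hoxa5, at 9.62 and 9.90 within the range of the YFP arrays, was fitted at -2.05 ± 0.38 and turned to 0.15 without them, Hoxc5 from -1.99 ± 0.56 to 1.61 and Lhx3 from -1.28 ± 0.29 to 0.29, while Mgat4c (2.88 ± 0.53) went to 0.12. Without Notch1ICD 10 replicate 2, Hey1 (adjusted p = 0.188), Neurod4 (0.12), Neurod1 (0.0726), Neurog2 (0.339), Hoxc5 (0.144) and Lhx3 (0.17) lost their call. Counts were 449 higher and 142 lower, 70 and 84 without the 6 arrays, 178 and 44 without batch terms and 201 (without Notch1ICD 10 replicate 2) to 585 in all with 1 array left out. Notch1ICD 30 against Notch1ICD 10 called 430 genes higher and 848 lower, 639 (without Notch1ICD 10 replicate 2) to 1082 in all with 1 array left out. There the balance turned, to 282 higher and 196 lower without the 6 arrays and 338 and 230 without batch terms. Calb1 was higher by 5.67 ± 0.30, Glra1 by 3.91 ± 0.40 and Ptn by 2.69 ± 0.35, and Isl1 fell by 1.05 ± 0.18 (adjusted p from 2.1e-16 to 0.00012). Notch1ICD 10 and NERT 10 shared 32 higher genes, where 1.76 would be met by chance, and 0 lower, with r = 0.208 across genes. Without the 6 arrays they shared 20, and r was -0.047.

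Hey1, a Notch-responsive repressor, was induced in CD2 cells (n = 2, batches 2 and 4) and called 50 genes higher and 22 lower. Besides Hey1 (2.76 ± 0.25, adjusted p = 4.77e-09) no named gene kept its call without every array. Hoxc5 (-2.39 ± 0.52), Hoxb6 (-1.11 ± 0.26) and the replication gene Pcna (-0.96 ± 0.23) lost it without the batch 4 Hey1 array (adjusted p = 0.763, 0.791 and 0.17), and also without the 6 other batch 4 arrays (-0.39, -0.19 and -0.88, adjusted p = 0.87, 0.901 and 0.245). Of 17 cell cycle genes 1 fell, and all 17 within the list (adjusted p = 7.09e-16, and 0.342 with estimation). Of 14 Hox paralogues 1 to 5, 2 fell, 11 within the list (adjusted p = 1.48e-12, and 0.208 with estimation). Without the 6 arrays that list was not called (adjusted p = 0.96), and within batch 2 Hoxc5 differed by -0.46. The count ran from 12 (without the batch 2 YFP array) to 872 (without the batch 2 Hey1 array), and was 2 without batch terms and 38 without the 6 batch 4 arrays.

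Klf5 in CD2 cells (n = 2) raised Ccn3 by 2.34 ± 0.21 (adjusted p = 1.35e-09) and called 54 genes higher and 8 lower. Nhlh1 (1.77 ± 0.34) and Pcdh8 (0.87 ± 0.16) lost their call without the batch 1 Klf5 array (adjusted p = 0.247 and 0.319), when 18 genes passed. The Klf6 line (n = 2), in which Klf6 did not rise, raised Crip1 by 1.27 ± 0.13 (adjusted p = 7.18e-08) and called 61 higher and 33 lower, 27 without the batch 2 Klf6 array and 180 without YFP replicate 2 of batch 3. Slc1a5 (1.52 ± 0.26) and Vsnl1 (-1.51 ± 0.29) lost their call without that Klf6 array (adjusted p = 0.101 and 0.11). The Zic1 line (n = 2) raised Timp4 by 2.50 ± 0.29, Igfbpl1 by 2.48 ± 0.30 and Gal, the galanin gene, by 2.82 ± 0.47, and Htr1a fell by 2.12 ± 0.29 (adjusted p from 1.53e-06 to 0.00103), with 39 higher and 19 lower, and 139 without batch terms.

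The other lines in CD2 cells changed few genes (n = 2 each). Vwc2 called 3 genes, Vwc2 itself, Chrm2 (-1.38 ± 0.25) and Doc2b (-1.03 ± 0.20), Btbd3 9, Tox 12, Zbtb7c 5 and Arid5b 2. Chrm2 also was lower in Btbd3 (-1.42 ± 0.25) and Tox (-1.26 ± 0.25), lines of batch 3 whose YFP arrays read 11.13 and 10.72 against 9.30 to 10.71 in the 13 other batch 3 arrays. It lost its call without replicate 1 of Vwc2, Btbd3 or Tox (adjusted p = 0.595, 0.347 and 0.71), and Doc2b without replicate 1 of Vwc2 (0.631). In batch 3 arrays alone 0 genes passed by limma for Btbd3 and Tox and 1 for Vwc2, and without YFP replicate 1 of batch 3 the 3 lines called 53 (Vwc2), 117 (Btbd3) and 35 (Tox). Unadjusted p was under 0.05 for 1552 genes in Btbd3 and 1565 in Tox. In Zbtb7c Apela fell by 2.88 ± 0.43 (adjusted p = 0.00146, and 0.257 without replicate 2 of that line), and 1 gene passed without the batch 2 YFP array. Arid5b called Pigo (0.63 ± 0.10, adjusted p = 0.00241) and Epn1 (0.57 ± 0.10, 0.145 without its batch 4 array and 0.123 without the 6), and 364 genes without its batch 3 array. Chd5 and Sfmbt2 changed 0 genes by limma, with 1022 and 1644 at unadjusted p under 0.05.

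The H4 line (n = 3, batches 2, 4 and 5) was compared with YFP as a parental control. It called 1 gene, Fpr-rs6 (-0.71 ± 0.13, adjusted p = 0.0464, and 0.601 without the batch 2 array), with 2124 at unadjusted p under 0.05, and 184 genes without its batch 4 array, whose Hoxa5 read 12.53 against 9.88 and 9.38 in the other H4 arrays. The single E3 array of batch 6 gave Isl1 at 12.80, Pou3f1 at 8.49 and Cdh9 at 6.04, and the YFP arrays of that batch 12.88 and 12.97, 8.45 and 8.48, and 5.86 and 5.87. It has no replicate and was not tested.

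Further list results follow, with adjusted p and, after it, adjusted p with an estimated correlation, which ended every call in this and the next paragraph. The phrenic list was lower in Hey1 (0.00635 and 0.357), Klf6 (0.00924 and 0.403), Tox (0.0208 and 0.491) and Klf5 (0.0249 and 0.511), with 1 of 12 genes called lower in Hey1 and 0 in the others by limma, and higher in H4 (0.0438 and 0.594, 0 of 12). The generic motor neuron list was lower in Btbd3 (0.0131 and 0.526), Zic1 (0.014 and 0.538) and Vwc2 (0.034 and 0.612) and higher in Sfmbt2 (0.00591 and 0.477). The lateral motor column list was higher in Zic1 (0.00439 and 0.105), H4 (0.0163 and 0.216), Pou3f1+DNLhx3 (0.023 and 0.266) and Btbd3 (0.035 and 0.325). Axon guidance genes were higher in Pou3f1+Lhx3 (0.0121 and 0.397), Notch1ICD 10 (0.028 and 0.491) and Sfmbt2 (0.0438 and 0.55) and lower in Flag-Pou3f1 (0.0193 and 0.471). Cadherins were higher in Pou3f1+Lhx3 (0.0121 and 0.266) and Notch1ICD 10 (0.028 and 0.397) and lower in Klf6 (0.0204 and 0.325) and DNLhx3 (0.03 and 0.403). BMP response genes were lower in Pou3f1 in CD2 cells (0.00439 and 0.266), Chd5 (0.00924 and 0.325) and Zbtb7c (0.024 and 0.471), and Notch targets in Pou3f1 in CD2 cells (0.037 and 0.612). Neurotrophic genes were higher in Klf5 (0.0178 and 0.166) and Notch1ICD 30 (0.0331 and 0.261).

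Hox paralogues 1 to 5 were lower in Klf6 (0.0239 and 0.812) and Pou3f1+Lhx3 (0.0325 and 0.817), and paralogues 6 to 13 in Notch1ICD 10 (0.00247 and 0.589), Pou3f1 in CD14 cells (0.0181 and 0.691) and H4 (0.0464 and 0.764). The hypaxial and preganglionic list was lower in Pou3f1+DNLhx3 (0.0193 and 0.126) and Pou3f1+Lhx3 (0.0333 and 0.208). The dorsal interneuron and sensory neuron list was lower in 5 comparisons (lowest in H4, 0.00129 and 0.589), and the mesoderm, endothelium and fibroblast list in 5 (lowest in Chd5, 0.0111 and 0.477). Neural progenitor genes were called in 6, 4 higher (lowest in Tox, 0.00278 and 0.589), and ventral interneuron genes also lower in Hey1 (0.0163 and 0.471) and Hoxa5 (0.034 and 0.55). The oligodendrocyte and astrocyte list was lower in Lhx3 (0.0181 and 0.325), the pluripotency list in H4 (0.0193 and 0.589), and the epithelial list in Zbtb7c (0.019 and 0.612), which was higher in Notch1ICD 10 (0.0197 and 0.612). Stress and apoptosis genes were called in 6, 3 higher (lowest in Hey1, 0.00413 and 0.612), and synaptic and mature neuron genes in 4, 3 higher (lowest in Notch1ICD 10, 0.0233 and 0.612). The neural crest list was called in 0 comparisons by limma's camera (lowest adjusted p = 0.0914, Hoxa5 in CD2 cells). The cell cycle list was called in 12, 8 lower and 4 higher.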

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

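Tests of array batch, mislabelled Hoxc6 or DNLhx3 arrays and the Lhx3 probe set were chosen after the results were seen. So were the spread in the tag test and the omission of 6 batch 4 arrays. Actc1 in the Pou3f1 arrays of CD2 cells had 1 array far from the others, batch 4 replicate 1 at 9.07 against 8.63 to 8.69 in the other 3 (Dixon's ratio 0.869). It was the only such value among 93 tested, where chance gives about 1 in 20.

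The effect of Pou3f1 differed between CD14 and CD2 cells for 2 genes, tested as an interaction. For Nr0b1 the difference was 1.93 ± 0.35 (adjusted p = 0.0294), with 2.14 in CD14 and 0.22 in CD2 cells. Its call was lost without 9 of the 14 arrays, 1 at a time (highest adjusted p = 0.644, without Pou3f1 replicate 1 in CD14 cells), and without the 6 batch 4 arrays (0.101). For Pou3f4 it was 1.02 ± 0.15 (adjusted p = 0.00114), with 0.30 in CD14 and -0.73 in CD2 cells, and adjusted p = 0.14 without YFP replicate 2 of batch 6 and 0.216 without batch terms.

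Hoxa5 and other Hox genes were higher in 6 of the 9 batch 4 arrays, which belong to 5 lines. A batch effect common to all 9 arrays is argued against, since the lowest Hoxa5 value of the 6 lay 2.24 above the highest of the other 3. Mislabelled Hoxc6 arrays are argued against too, as Hoxc6 in the 6 (7.33 to 8.12) lay at least 1.06 below the labelled Hoxc6 arrays, although it lay above the YFP arrays (up to 7.00), and the batch 4 difference of H4 correlated with the effect of Hoxc6 added to Pou3f1 (r = 0.438, 154 of the 200 largest differences with the same sign). Retinoid or caudal patterning of the culture may have differed. Its panel's median difference was 0.19 over the 5 lines (-0.07 to 0.41, -0.18 in Hey1). Rarb (0.74 to 2.27), Nrip1, Tshz1 and Meis1 rose in all 5. Outside the panel so did Cyp26b1 (1.65 to 2.45) and Dhrs3 (1.35 to 2.42), at 0.06 and -0.13 in Hey1. Crabp2 and Rdh10 fell in all 5 and Hey1, leaving it open.

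Flag-Pou3f1 and Pou3f1 in CD14 cells differed in 440 genes. A tag that changes Pou3f1 activity stays open. The 417 genes that Pou3f1 changed in CD2 cells had a median of -0.052 between lines, signed by that direction (quartiles -0.25 to 0.11, 3 called in that direction and 22 against). A differing share of small nucleolar RNA may contribute. The 51 genes had a median of 0.293 (quartiles 0.10 to 0.61, 5 called higher), and this stays open because the same median was 0.363 and 0.427 for Pou3f1+Hoxa5 and Pou3f1+Hoxc6.

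DNLhx3 called 815 genes with no called rise of Lhx3. Mislabelled arrays are argued against, since the effect correlated at r = 0.52 with that of Pou3f1+DNLhx3 over Pou3f1, with no array shared. Of called genes, 106 were higher in both (3.78 by chance), 136 lower in both (4.82) and 0 opposite. A probe set that does not read the induced form stays open. The smaller Lhx3 rise in the 2 Lhx3 lines exceeded the larger change in the 2 DNLhx3 lines by 2.71, yet Lhx3 in Pou3f1+DNLhx3 (0.60) was called in 4 alternatives (adjusted p = 0.00146, 0.0121, 0.014 and 0.017). The dominant-negative form named in the label was not tested as the cause.

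Other splits of the same arrays were run where both groups had at least 3 arrays. For Pou3f1 in CD2 cells 1 of 35 splits, the real one, gave 417 genes and the highest other 132, so chance is argued against, not excluded. For H4, 14 of 35 splits gave at least the real count of 1, so chance cannot be excluded. The highest other, 2526, set both batch 2 arrays and YFP replicate 2 of batch 3 against the rest, so counts reflect sample structure too.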

How the results depend on the processing

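All alternatives except leaving out batch 4 arrays were planned. Of 466 named gene values, 427 were called. Their direction turned in 11 instances, all in Notch1ICD 10 except Bmp4 in Pou3f1+Lhx3 over Pou3f1, and 22 more values turned sign without a call in either fit. The 11 lost their call as well, and the counts of losses below leave them out. Without batch terms 108 of the 466 lost and 4 gained a call in the same direction. Numbers lost and gained were 0 and 1 of 459 with dim genes left out, 13 and 0 with quantile normalization once more, 1 and 0 with the mean of all clusters, and 36 and 8 without the 6 arrays. They were 26 and 8 of 438 without batch 4, 73 and 6 of 462 with CD2 and CD14 arrays apart, 21 and 5 of 302 in 1 batch, and 454 and 2 of 2781 when 1 array was left out. Where an arm kept 1 array, that array was assumed to vary like the other groups. Of 648 list tests, 112 were called, and 14 with an estimated correlation, 122 without batch terms, 93 with dim genes left out, 96 with quantile normalization once more and 126 without the 6 arrays. Without batch 4, 118 of 624 were called. The cause of these shifts was not tested. Signal over background could not be examined from summarised values.

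Genes called in the model of all arrays were Arid5b 2, Btbd3 9, Chd5 0, DNLhx3 815, H4 1, Hey1 72, Hoxa5 0, Hoxc6 468, Klf5 62, Klf6 94, Lhx3 759, Notch1ICD 10 591, Notch1ICD 30 1210, Pou3f1 CD2 417, Sfmbt2 0, Tox 12, Vwc2 3, Zbtb7c 5 and Zic1 58 in CD2 cells. In CD14 cells they were Flag-Pou3f1 486, NERT 10 83, NERT 30 938, Pou3f1+DNLhx3 798, Pou3f1+Hoxa5 1180, Pou3f1+Hoxc6 1790, Pou3f1+Lhx3 785 and Pou3f1 CD14 61. Between lines they were Pou3f1+Hoxa5 over Pou3f1 687, Pou3f1+Hoxc6 over Pou3f1 1788, Pou3f1+DNLhx3 over Pou3f1 420, Pou3f1+Lhx3 over Pou3f1 100, Flag-Pou3f1 over Pou3f1 440, Notch1ICD 30 over Notch1ICD 10 1278, NERT 30 over NERT 10 754 and the difference of Pou3f1 effects 2. Values that follow are those that differed by more than 1.5 times, or passed the threshold on 1 side only. For Chd5, Hoxa5 and Sfmbt2, at 0 by limma, unadjusted p was under 0.05 for 1022, 2071 and 1644 genes.

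Without batch terms the counts in CD2 cells were Arid5b 0, Btbd3 0, DNLhx3 458, H4 0, Hey1 2, Hoxa5 123, Klf5 38, Klf6 11, Notch1ICD 10 222, Tox 0, Vwc2 1, Zbtb7c 3 and Zic1 139. In CD14 cells they became Flag-Pou3f1 318, NERT 10 202, NERT 30 1864 and Pou3f1 CD14 168, and between lines Pou3f1+Hoxa5 over Pou3f1 95, Pou3f1+Hoxc6 over Pou3f1 641, Pou3f1+DNLhx3 over Pou3f1 187, Pou3f1+Lhx3 over Pou3f1 522, Flag-Pou3f1 over Pou3f1 0, Notch1ICD 30 over Notch1ICD 10 568, NERT 30 over NERT 10 319 and the difference of Pou3f1 effects 1. Genes shared by the Pou3f1 effects in CD2 and CD14 cells numbered 73 (38 in the model of all arrays) and by Notch1ICD 10 and NERT 10 50 (32), and the phrenic list gave adjusted p = 1 by Fisher's exact test in Notch1ICD 10. In Notch1ICD 10, Mgat4c turned to -0.18, Hoxa5 to 0.25, Hoxc5 to 0.77, Hoxb5 to 0.15 and Lhx3 to 0.18, and in Pou3f1+Lhx3 over Pou3f1 Bmp4 turned to 0.046.

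Replicate numbers did not pair the arrays throughout: the deviations of same-numbered arrays correlated above 0.1 in 6 of 15 pairs of groups in batch 3 (Btbd3, Vwc2 and Tox at 0.273 to 0.565), 1 of 1 in batch 4, 2 of 10 in batch 6 and 1 of 3 in batch 7. With a block for each replicate number within a batch, in place of the batch, the counts were Arid5b 0, Btbd3 1, Hey1 42, Hoxc6 197, Klf6 31, Lhx3 83, Pou3f1 CD2 215, Sfmbt2 1 and Zic1 28 in CD2 cells, Pou3f1+Hoxa5 266 in CD14 cells, and Pou3f1+Hoxa5 over Pou3f1 97 and the difference of Pou3f1 effects 0 between lines. The phrenic list by Fisher's exact test gave adjusted p = 0.225 in Hoxc6 and 0.00545 in NERT 30, 72 of 433 named gene values lost their call, and 119 of 576 list tests were called.

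With dim genes left out, which left 11607 genes to test, counts were Arid5b 9, H4 0, Hey1 134, Klf6 152 and Lhx3 463, and the phrenic list by Fisher's exact test gave adjusted p = 0.0312 in Hey1, 0.0613 in Hoxc6, 0.0922 in Notch1ICD 30 and 0.0933 in Flag-Pou3f1. With quantile normalization once more they were Arid5b 11, Btbd3 3, H4 0, Hoxa5 5, Klf6 158 and Zbtb7c 10, with adjusted p = 0.0409 by Fisher's exact test for the phrenic list in NERT 30. That scaling moved the share of higher genes from 100% to 54.6% in Arid5b, 22.2% to 0% in Btbd3, 43.9% to 54.9% in Lhx3, 76.0% to 62.7% in Notch1ICD 10 and 60% to 80% in Zbtb7c. It moved it from 52.7% to 41.5% in Flag-Pou3f1 and from 33.7% to 43.7% in Notch1ICD 30 over Notch1ICD 10. Of the 25 comparisons with at least 50 calls in both fits, the majority of higher or lower calls turned in 15 under some alternative. Without batch terms it turned from 260 higher and 157 lower to 234 and 291 in Pou3f1 CD2, 333 and 426 to 368 and 196 in Lhx3, 399 and 416 to 281 and 177 in DNLhx3 and 373 and 381 to 210 and 109 in NERT 30 over NERT 10. Without the 6 arrays it turned from 240 and 228 to 152 and 239 in Hoxc6.

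Without the 6 batch 4 arrays the counts were Arid5b 7, Btbd3 15, H4 128, Hey1 38, Hoxa5 85, Klf6 224, Notch1ICD 10 154, Tox 37, Vwc2 14, Zbtb7c 12 and Zic1 92 in CD2 cells. They were Flag-Pou3f1 789, NERT 10 135 and Pou3f1 CD14 133 in CD14 cells, and Pou3f1+Lhx3 over Pou3f1 166, Flag-Pou3f1 over Pou3f1 683, Notch1ICD 30 over Notch1ICD 10 478 and the difference of Pou3f1 effects 1 between lines. Shared genes numbered 93 for Pou3f1 and 20 for Notch1ICD 10 and NERT 10. The phrenic list by Fisher's exact test gave adjusted p = 0.00445 in Hoxa5, 1 in Notch1ICD 10 and 0.00714 in Pou3f1+Lhx3. In Notch1ICD 10, Neurog2 turned to 0.086, Hoxa5 to 0.15, Hoxc5 to 1.61, Hoxb5 to 0.77 and Lhx3 to 0.29, and the Hox paralogues 1 to 5 list was called higher (adjusted p = 0.000867).

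Without all 9 batch 4 arrays, which leaves no value for Notch1ICD 10, the counts were Arid5b 7, Btbd3 16, H4 146, Hey1 42, Hoxa5 82, Klf6 206, Tox 37, Vwc2 16, Zbtb7c 8 and Zic1 88 in CD2 cells. For CD14 cells they were Flag-Pou3f1 782, NERT 10 139 and Pou3f1 CD14 132, and between lines Pou3f1+Lhx3 over Pou3f1 159, Flag-Pou3f1 over Pou3f1 730 and the difference of Pou3f1 effects 1. The Pou3f1 effects shared 92 genes, and the phrenic list by Fisher's exact test gave adjusted p = 0.00399 in Hoxa5 and 0.00637 in Pou3f1+Lhx3.

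Fitted apart, CD2 arrays gave Arid5b 0, Btbd3 0, DNLhx3 356, H4 0, Hey1 1, Hoxc6 138, Klf5 25, Klf6 13, Lhx3 130, Notch1ICD 10 233, Notch1ICD 30 751, Pou3f1 CD2 134, Tox 0, Vwc2 1, Zbtb7c 1 and Zic1 19. CD14 arrays gave Flag-Pou3f1 3180, NERT 10 1009, NERT 30 3717, Pou3f1+DNLhx3 2194, Pou3f1+Hoxa5 4296, Pou3f1+Hoxc6 4897, Pou3f1+Lhx3 2292 and Pou3f1 CD14 578. Between lines the counts were Pou3f1+Hoxa5 over Pou3f1 3664, Pou3f1+Hoxc6 over Pou3f1 5618, Pou3f1+DNLhx3 over Pou3f1 1502, Pou3f1+Lhx3 over Pou3f1 427, Flag-Pou3f1 over Pou3f1 3307, Notch1ICD 30 over Notch1ICD 10 599 and NERT 30 over NERT 10 2604. These counts fell in CD2 cells and rose in CD14 cells, so p-values of the joint fit may be too small for CD2 lines.

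Batch 3 arrays alone gave Btbd3 0, DNLhx3 263, Notch1ICD 30 557, Tox 0 and Vwc2 1. Batch 6 arrays alone gave Flag-Pou3f1 2227, Pou3f1+DNLhx3 1667, Pou3f1+Hoxa5 3386, Pou3f1+Hoxc6 4115 and Pou3f1 CD14 302 over YFP, and Pou3f1+Hoxa5 over Pou3f1 2685, Pou3f1+Hoxc6 over Pou3f1 4726, Pou3f1+DNLhx3 over Pou3f1 973 and Flag-Pou3f1 over Pou3f1 2351. Batch 7 arrays alone gave NERT 10 263, NERT 30 2788, Pou3f1+Lhx3 1568 and NERT 30 over NERT 10 1897. With the H4 and E3 arrays pooled with YFP the counts were Hey1 440, Hoxa5 12, Klf5 116, Klf6 323, Lhx3 377, Notch1ICD 10 998, Pou3f1 CD2 1076, Tox 7, Vwc2 1, Zbtb7c 95 and Flag-Pou3f1 830.

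With each array left out in turn, the counts ran as follows in CD2 cells: Arid5b 1 to 364, Btbd3 0 to 117, Chd5 0 to 1, DNLhx3 333 to 1784, H4 0 to 184, Hey1 12 to 872, Hoxa5 0 to 36, Klf5 18 to 70, Klf6 27 to 180, Lhx3 25 to 1343, Notch1ICD 10 201 to 585, Notch1ICD 30 703 to 1231, Pou3f1 CD2 185 to 665, Sfmbt2 0 to 5, Tox 5 to 35, Vwc2 1 to 53 and Zbtb7c 1 to 12. In CD14 cells the ranges were Flag-Pou3f1 40 to 435, NERT 10 28 to 82, NERT 30 371 to 885, Pou3f1+DNLhx3 423 to 768, Pou3f1+Hoxa5 278 to 1116, Pou3f1+Hoxc6 715 to 1716, Pou3f1+Lhx3 354 to 749 and Pou3f1 CD14 16 to 58. Between lines they were Pou3f1+Hoxa5 over Pou3f1 103 to 252, Pou3f1+Hoxc6 over Pou3f1 573 to 914, Pou3f1+DNLhx3 over Pou3f1 192 to 289, Pou3f1+Lhx3 over Pou3f1 52 to 74, Flag-Pou3f1 over Pou3f1 53 to 115, Notch1ICD 30 over Notch1ICD 10 639 to 1082, NERT 30 over NERT 10 295 to 431 and the difference of Pou3f1 effects 0 to 2. Hoxc6 (345 to 517) and Zic1 (40 to 78) stayed within 1.5 times of their counts. The 503 genes shared by Notch1ICD 30 and NERT 30 were 507 to 618 in the 6 alternatives run for them.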

Other observations

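The pairs of comparisons below share no array and were chosen after the results were seen. Hoxc6 alone in CD2 cells and Hoxc6 added to Pou3f1 in CD14 cells raised 68 genes in both (11.2 by chance), among them Aldh1a2, Cdh7, Cdh9 and Cdh20. They lowered 68 in both (9.8 by chance), among them Cartpt, Eya1 and Zeb2, and called 19 in opposite directions (r = 0.185 and rho = -0.0418 across genes). Lhx3 alone in CD2 cells and Lhx3 added to Pou3f1 raised 21 in both (1.17 by chance), with Tac1 and Hcrtr2 among them. They lowered 13 (0.641 by chance), with Sst, Htr1a and Shisa6, and called 1 in opposite directions (r = 0.106, rho = -0.0297).

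Lhx3 and its dominant-negative form also had called genes in common. Lhx3 in CD2 cells and DNLhx3 added to Pou3f1 raised 26 in both (3.16 by chance), among them Rpp25, Kcnip4, Lypd1, Reln and Epha4. They lowered 38 (4.94 by chance) and called 12 in opposite directions (r = 0.0707, rho = -0.062). DNLhx3 in CD2 cells and Lhx3 added to Pou3f1 raised 12 (1.4 by chance), lowered 15 (0.626 by chance) and called 1 in opposite directions (r = 0.175, rho = 0.117).

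The mean of the cell cycle list ran from 9.27 to 10.73 over the 4 YFP arrays in CD2 cells and from 9.49 to 10.69 over the 4 in CD14 cells. It was 11.05 and 11.13 in Notch1ICD 30, and 11.08 and 11.15 in NERT 30.

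The 2 induced E3 arrays of batch 0 entered no comparison. Pou3f1 read 7.75 and 7.72, Isl1 12.95 and 12.96, Pcdh10 10.46 and 10.50, Cdh9 5.44 and 5.53 and Hoxa5 9.22 and 9.18.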
